A study of Mus musculus with 15 samples.

How the data were processed

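RNA was sequenced from 6DT1 cells, a mouse mammary cancer cell line of FVB/N1 background, as wild-type cells and as cells in which Clic4 had been knocked out. Each genotype was left untreated or exposed to 1 µM hydrogen peroxide (H2O2) for 24 h. RNA was isolated with an RNeasy kit on a QIAcube, and TruSeq Stranded mRNA libraries were sequenced as read pairs on a NextSeq, per the labels' protocols. The 15 libraries fell into 4 groups by their titles: untreated knockout (replicates 1 to 4), H2O2-treated knockout (replicates 5, 7 and 8), untreated wild type (replicates 9 to 12) and H2O2-treated wild type (replicates 13 to 16). The labels hold no replicate 6. Replicate 9 was titled, described and sourced as untreated wild type, while its genotype field said knockout. It was kept as wild type.

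The deposited count table holds expected counts per gene symbol, which the authors made with tools that the submitters' processing notes name as cutadapt, STAR and RSEM on genome build mm10, without versions, roles or settings. All deposited counts are whole numbers, although RSEM estimates fractional counts, so rounding was done before deposit. The deposited RPKM table holds the same libraries scaled by gene length and library size (reads per kilobase per M counts). Over 9805 genes with more than 50 counts in every library, each RPKM value equalled the count divided by 1 constant per gene and 1 per library, with a largest relative deviation of 9.3e-15. There are 55341 symbols with counts and 53528 with RPKM values, so 1813 are absent from the latter. No column was left without a sample, and no annotation version or filter is stated for either table. All 55341 symbols were found in GENCODE M21, from which chromosomes and positions on mm10 were taken.

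Differences were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes with too few counts were removed with filterByExpr, which left 13085 genes holding 99.917% of all counts. Libraries were scaled by TMM, and 1 quasi-likelihood model with robust dispersion was fitted to the 4 group means, with 11 residual degrees of freedom. The contrasts were knockout against wild type without treatment, knockout against wild type with H2O2, H2O2 against untreated in each genotype, the mean of those 2 treatment effects, and their difference (the interaction). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes under 0.05 were called. Every adjusted p of a gene comes from edgeR's quasi-likelihood test with that adjustment unless another tool is named. Log2 fold changes come from the same fit, with an approximate standard error (SE). Expression is normalised CPM (counts per M, scaled by TMM) as mean ± SD. Where a group held 0 counts of a gene, SE is no guide to precision and the difference is a lower bound with the group at 3 counts. Where it held 1 to 3, or where both groups could be counted but 1 was very low, the ratio of CPM is given with its 95% exact binomial interval.

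Before the data were examined, 40 gene lists were fixed from general knowledge of the pathways, together with the design, the rule for naming genes and the alternatives. The lists hold 806 genes, of which 800 were in the count table and 692 were tested. The adipocyte list had no tested member, which left 39 lists: the CLIC family, subunits encoded by mitochondrial DNA, nuclear subunits of complex I and of complexes II to V, TCA cycle, glycolysis, fatty acid oxidation, uncoupling proteins and carriers, mitochondrial dynamics and mitophagy, mitochondrial biogenesis, NRF2 targets, peroxide and superoxide removal, p53 targets, BCL2 family, integrated stress response, endoplasmic reticulum chaperones, heat shock proteins, hypoxia-inducible genes, DNA replication, mitosis, epithelial and mesenchymal genes, extracellular matrix, matrix proteases, integrins and focal adhesion, actin cortex, TGF-beta, YAP, type I interferon, MHC class I, NF-kB targets, immediate early genes, cholesterol biosynthesis, ribosomal proteins, mammary driver and luminal genes, and markers of basal, fibroblast, immune and endothelial cells. Some genes are in more than 1 list. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other tested genes, adjusted over the lists of a comparison. Camera with a correlation estimated from the data and fry, which asks whether a list's genes move 1 way on balance, were run beside it.

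The genes named were set by rule. Clic4 and the other tested CLIC genes were given in every comparison. For the untreated genotype comparison, the 12 genes with the largest and the 12 with the smallest log2 fold change were taken among called genes with a mean of at least 5 CPM in the higher group and no overlap of replicates. For the other comparisons the number was 8 each way, and for the interaction 5. Where fewer than 5 passed, those that passed and the 5 with the smallest p were given. From each called list the 3 members with the smallest p in its direction were added, and 2 members each from the oxidative phosphorylation, uncoupling, NRF2 and peroxide lists. Predicted genes were counted but not named by the rule. An item that the rule takes is not reported here. Any other gene named was chosen after its values were seen, and list members are not named again for the mean treatment effect and the interaction. Overlap between the 2 genotype comparisons, which share no libraries, was counted and set beside the overlap of independent lists.

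The procedure was tested on simulated data drawn with the real dispersions and library sizes, the same mean in every group and 200 genes changed. In the untreated genotype comparison (12835 genes), 55.1%, 77.6% and 88% of genes changed 1.25-fold, 1.5-fold and 2-fold were recovered, with 13 false among 191 calls. With H2O2 (12851 genes) the values were 48%, 77.6%, 88% and 10 of 183. For H2O2 in wild-type cells (12849) they were 59.2%, 87.8%, 98% and 9 of 196. For H2O2 in knockout cells (12840) they were 56%, 70%, 81.6% and 10 of 181. For the mean treatment effect (12850) they were 78%, 88%, 93.9% and 12 of 214. For the interaction (12854) they were 36.7%, 72%, 87.8% and 10 of 169. None of 38 unchanged lists was called in the 6 simulations, where genes vary independently, while other splits of the real libraries called a median of 5.5 to 9.

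Alternatives fixed beforehand were scaling by DESeq2's size factors, no low-count filter, a stricter one (5 CPM in at least 3 libraries), a required log2 fold change of at least 1, the DESeq2 1.42.0 Wald test, limma-voom, limma-trend on log2(RPKM + 0.1) and log2(RPKM + 1), a fit of only the groups compared, and leaving out each library in turn. Limma-voom was planned on fractional counts and was run on the deposited whole counts. Leaving out replicates 4 and 9 together was added after the data were seen. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Total counts per library ran from 12.31 M to 16.03 M. Sequence reads were not analysed, so any altered part of Clic4 and allele differences were not examined, and isoforms were not separated.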

Results

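The experiment asked how loss of CLIC4, a chloride intracellular channel protein found in several compartments including mitochondria, alters transcription in 6DT1 mouse mammary cancer cells, and whether it alters the answer to a mild oxidant. Wild-type and Clic4-knockout cells were left untreated or given 1 µM H2O2 for 24 h, and their polyadenylated RNA was sequenced. The 4 untreated knockout libraries held 13.27, 14.88, 16.03 and 15.12 M counts, and the 3 treated ones 14.50, 14.71 and 12.31 M. The 4 untreated wild-type libraries held 14.66, 13.95, 14.29 and 15.62 M counts, and the 4 treated ones 15.72, 15.84, 13.38 and 13.82 M. After removal of genes with few counts, 13085 genes were tested with edgeR's quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method. The labels do not state whether replicates were grown independently, or how many knockout clones were used, so p-values measure spread between these samples.

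The gene that was knocked out was read first in every library. Clic4, on the minus strand of chromosome 4 (135213969–135272814, mm10), stood at 326.7, 324.2, 318.1 and 315.9 CPM in the untreated wild-type libraries and 314.5, 313.0, 316.8 and 315.1 CPM in the treated ones. In knockout cells it stood at 75.1, 74.0, 72.0 and 64.2 CPM without treatment and 75.9, 68.4 and 71.1 CPM with H2O2. Clic4 mRNA was therefore reduced and not absent, and gene counts cannot show whether the remaining transcripts are altered by the knockout. Its log2 fold change was −2.17 (SE 0.043, adjusted p 9.88e-26) without treatment and −2.13 (SE 0.048, adjusted p 2.92e-24) with H2O2. H2O2 left Clic4 unchanged within detection in wild-type (log2 −0.03, adjusted p 0.955) and in knockout cells (log2 0.01, adjusted p 0.982). Replicate 9, whose genotype field reads knockout against its title, carried the wild-type level of Clic4.

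**Figure D1:**
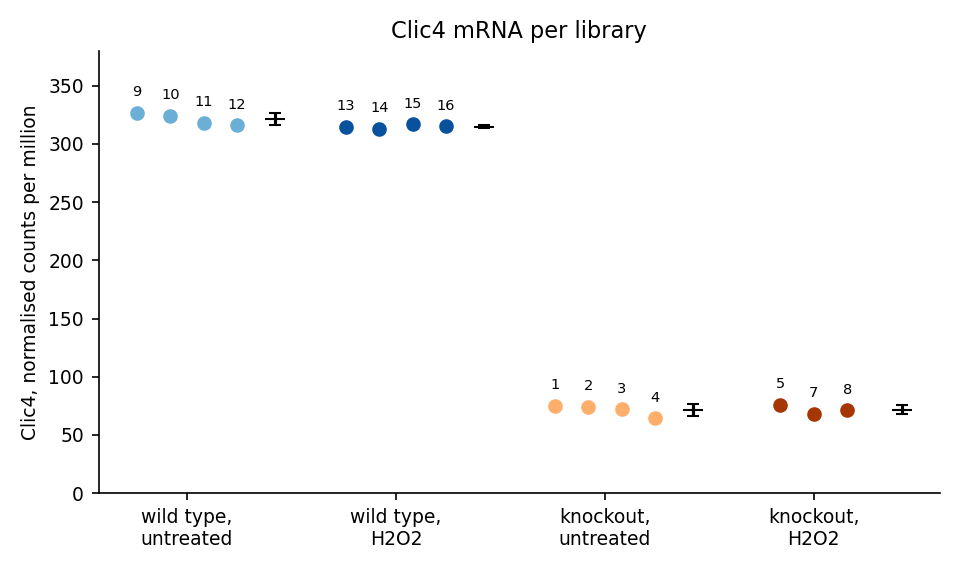
Clic4 in normalised CPM in each of the 15 libraries by genotype and treatment, with mean and SD per group. Untreated means were 321 CPM in wild-type and 71.3 CPM in knockout cells.

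Libraries separated by genotype and scarcely by treatment. Correlation of log2 CPM was at least 0.9885 between libraries of a genotype and at most 0.9355 between genotypes, counting genes that are not independent of each other. The first principal component carried 80.77% of the variance and the next 2.136%. Replicates varied more than counting error alone, with chi-square per degree of freedom between 2.07 and 8.15 over 21 pairs of replicates. The common biological coefficient of variation was 4.958%, which lets small differences pass the test.

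Which genes differ between knockout and wild-type cells without treatment? The knockout expressed genes that were nearly silent in the wild-type line, among them the stress cytokine Gdf15, the Wnt ligand Wnt10a and the CD40 receptor. It had lost others outright, among them the branched-chain aminotransferase Bcat1 and the integrin chain Itga8. Genes of DNA replication and mitosis were higher, interferon-stimulated genes were lower, and targets of NF-kB were higher by camera at its preset correlation. Of these lists the interferon one alone held with the estimated correlation (adjusted p 0.0376). Of 13085 genes, 8746 differed (66.84%), 4439 higher and 4307 lower in knockout cells. Most differences were small: 5555 of them were under 1.5-fold and 1745 reached 2-fold, of which 890 were higher and 855 lower.

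The largest increases were in genes almost absent from wild-type cells. Gdf15, a distant TGF-beta family member induced by cell stress (chromosome 8, 70629393–70632456, mm10), had 1008 counts over the untreated knockout libraries and 0 in wild type, at least 339.1-fold more (log2 10.96, SE 0.779, adjusted p 9.33e-07). It averaged 17.1 ± 5.87 CPM. Tmem26, a transmembrane protein, reached 10.4 ± 0.676 CPM from 0, at least 203.2-fold (log2 10.23, adjusted p 4.55e-17). Crtam, an adhesion molecule known from cytotoxic T cells, was at least 148.7-fold higher (log2 9.78). For Wnt10a the ratio was 719.6 (95% interval 128.7 to 28460, log2 8.91, adjusted p 5.03e-06), from 0.0169 to 12.3 ± 4.68 CPM. For Fbp2, the muscle fructose bisphosphatase, the ratio was 596.5 (106.6 to 23600, log2 8.63). For the collagen chain Col8a1 it was 435.5 (120.2 to 3602, log2 8.44). Tnfsf13b, which encodes the B-cell survival factor BAFF, had a ratio of 356.9 (121.8 to 1734, log2 8.26). Fkbp10, a prolyl isomerase that folds collagen, had 350.2 (62.44 to 13870, log2 7.86). The aminopeptidase N gene Anpep rose from 0.376 ± 0.101 to 88.8 ± 10.4 CPM, a ratio of 238.5 (157.4 to 380.9, log2 7.86, SE 0.131, adjusted p 3.5e-27). Cd40 rose from 0.115 to 27 ± 2.97 CPM (ratio 227.1, 110 to 565.7, log2 7.73), and the small heat shock protein Hspb7 had a ratio of 228.1 (88.77 to 838.9, log2 7.66). Lgals7, a galectin of stratified epithelia, rose from 1.2 ± 0.0695 to 226 ± 17 CPM, 188.0-fold (149 to 240.9, log2 7.54, adjusted p 1.39e-22). These bounds and intervals cover counting error only, and a fitted log2 against a group near 0 counts is not a bound.

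Decreases ran as deep. Fndc3c1 (chromosome X, 106420041–106485401, mm10) fell from 22.9 ± 0.967 CPM to 0, at least 445.9-fold (log2 −11.38, SE 0.249, adjusted p 2.61e-21). Mid2, a microtubule-associated ubiquitin ligase, fell at least 394.0-fold (log2 −11.20), and Itga8, the integrin alpha chain that pairs with beta chain Itgb1, fell at least 353.7-fold from 18.2 ± 0.931 CPM (log2 −11.04). The thyroid hormone receptor gene Thrb fell at least 239.1-fold (log2 −10.48) and Trim44, of the tripartite motif family, at least 234.8-fold (log2 −10.45). Ankrd29 fell at least 196.5-fold (log2 −10.20), Plcl1 at least 169.4-fold (log2 −9.98) and the transcription factor Gata4 at least 169.4-fold (log2 −9.98). Among ephrin receptors, Ephb2 fell at least 183.6-fold (log2 −10.10) and Ephb6 at least 160.2-fold (log2 −9.90). Bcat1 (chromosome 6, 144993835–145076184, mm10) fell from 34.3 ± 3 to 0.0158 CPM, a ratio of 1998 (358.1 to 78940, log2 −10.38, adjusted p 2.13e-24). Lcp1, the leukocyte actin-bundling protein L-plastin, fell from 22.4 ± 5.9 to 0.0191 CPM, a ratio of 1309 (234.5 to 51740, log2 −9.77). Wild-type replicate 9 held 31.12 CPM of Lcp1 against 18.35 to 20.35 in the others, together with transcripts typical of blood cells.

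Other CLIC genes moved little in absolute terms. Clic1, on chromosome 17, rose from 309 to 342 CPM (log2 0.14, SE 0.034, adjusted p 0.00047). Clic5 rose from 0.269 to 1.15 CPM (log2 2.08, SE 0.451, adjusted p 0.000205), and Clic3 and Clic6 had too few counts to test. By camera the CLIC list of 3 tested genes ranked lower (adjusted p 0.0119), as its direction was set by Clic4. Its median log2 was 0.14 and its mean 0.02, with 2 genes higher and 1 lower, also when adjusted over the list alone, and with an estimated inter-gene correlation adjusted p was 0.103.

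Camera called 14 of the 39 gene lists at its preset inter-gene correlation and 1 when the correlation was estimated from the data, while fry called 32. In the DNA replication list 29 of 30 genes were higher and 0 lower (median log2 0.97, camera adjusted p 6.96e-22, estimated-correlation adjusted p 0.0745; 29 and 0 adjusted over the list alone). Rrm2, the ribonucleotide reductase subunit, rose from 115 ± 5.58 to 294 ± 24.9 CPM (log2 1.36), the helicase subunit Mcm7 from 70.3 ± 1.25 to 146 ± 7.43 CPM (log2 1.05), and Uhrf1, which guides maintenance DNA methylation, from 93.7 ± 4.7 to 218 ± 7.55 CPM (log2 1.22, SE 0.04, adjusted p 1.75e-20). Gins2 was the 1 member that did not pass (log2 0.12, adjusted p 0.0875, named after its values were seen). All 30 mitosis genes were higher, also adjusted over the list alone (median log2 0.84, camera adjusted p 2.72e-17, estimated-correlation adjusted p 0.103). Among them the cytokinesis scaffold Anln rose from 159 ± 9.44 to 306 ± 17.9 CPM (log2 0.95), cyclin A2 (Ccna2) from 44.2 ± 2.44 to 109 ± 8.72 CPM (log2 1.30), and survivin (Birc5) from 26.7 ± 2.72 to 68.4 ± 5.43 CPM (log2 1.35). All 48 ribosomal protein genes were higher by a median log2 of 0.34, also adjusted over the list alone (camera adjusted p 6.48e-07, estimated-correlation adjusted p 0.548). Rpl22 rose most clearly, from 268 ± 7.29 to 603 ± 33.6 CPM (log2 1.17), beside Rpl3 (log2 0.58) and Rpl11 (log2 0.50). Ribosomal protein genes have many pseudogenes that share their reads, which leaves single members uncertain.

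Interferon-stimulated genes fell as a group. In this list 26 of 27 genes were lower and 0 higher (median log2 −1.57, camera adjusted p 9.29e-20, estimated-correlation adjusted p 0.0376), and the same 26 passed adjusted over the list alone. Ifi44 fell from 20.6 ± 1.1 to 0.917 ± 0.249 CPM (log2 −4.47, SE 0.129, adjusted p 9.69e-22). The ubiquitin-like modifier Isg15 fell from 41.1 ± 1.8 to 12.3 ± 1.23 CPM (log2 −1.74), and its protease Usp18 from 26.6 ± 1.19 to 4.53 ± 1.22 CPM (log2 −2.55). Only Ifit2 did not pass (log2 0.11, adjusted p 0.354, named after its values were seen).

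Targets of NF-kB went the other way. Of 23 tested, 22 were higher and 1 lower in knockout cells, also adjusted over the list alone (median log2 2.18, camera adjusted p 5.99e-05, estimated-correlation adjusted p 0.548). Tnf rose from 0.0169 to 2.21 ± 0.649 CPM, a ratio of 129.2 (22.77 to 5142, log2 6.43). The adhesion receptor Vcam1 rose from 19.9 ± 2.03 to 90.1 ± 16 CPM (log2 2.18) and Birc3, an inhibitor of apoptosis that NF-kB induces, from 9.77 ± 0.378 to 23 ± 3.46 CPM (log2 1.23, SE 0.098, adjusted p 1.18e-11). The lower member was the chemokine Ccl5 (log2 −1.37), named after its values were seen. Untreated knockout replicate 4 stood apart in this list: Cxcl1 was at 177.4 CPM there against 651.2 to 779.4 in the other 3, Ccl2 at 152.5 against 446.6 to 528.4, and Csf3 at 6.68 against 38.1 to 55.4. These 3 genes were also chosen after the values were seen. Immediate early genes were mostly higher, 18 of 21 with 1 lower, also adjusted over the list alone (median log2 0.67, camera adjusted p 0.0035, estimated-correlation adjusted p 0.367). They included Egr2, a zinc finger factor that rose from 0.845 ± 0.0777 to 4.88 ± 0.363 CPM (log2 2.51), and the phosphatases Dusp1 (log2 1.00) and Dusp6 (log2 0.55), against Dusp5 (log2 −0.21).

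**Figure D2:**
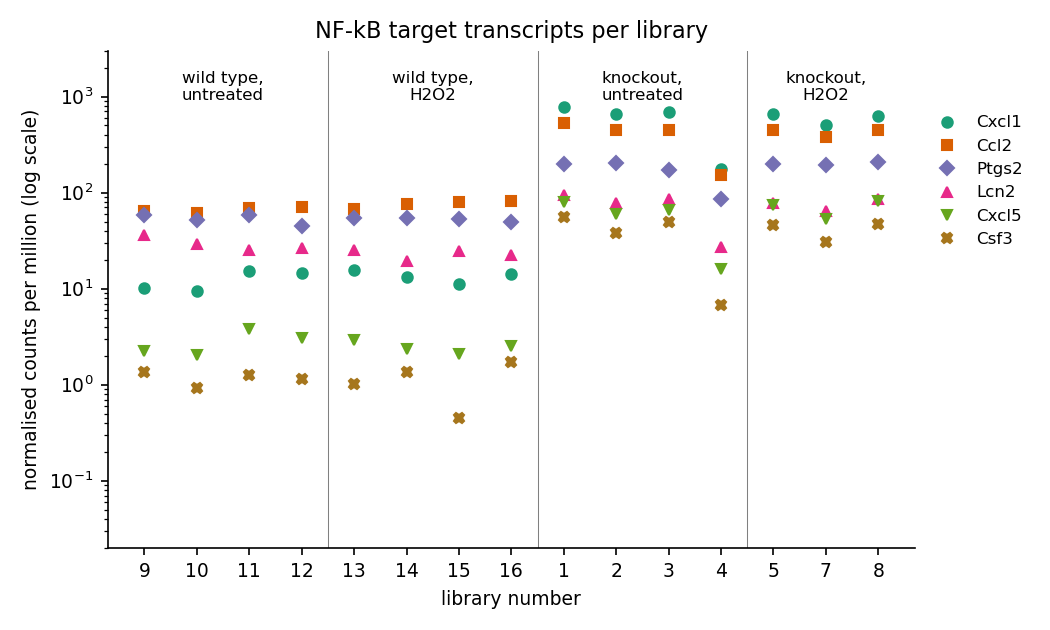
Normalised CPM of 6 NF-kB target genes in each library on a log scale. Untreated knockout replicate 4 held 177.4 CPM of Cxcl1 against 651.2 to 779.4 in the other untreated knockout libraries.

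Mesenchymal genes were mostly higher, and epithelial genes went both ways, and the numbers of genes were the same adjusted over the list alone. Dsp, the desmosomal plaque protein desmoplakin, fell from 498 ± 6.49 to 75.8 ± 4.56 CPM (log2 −2.72, SE 0.041, adjusted p 2.75e-28), Krt18 from 334 ± 1.65 to 153 ± 4.89 CPM (log2 −1.12), and Jup, plakoglobin, had a log2 of −0.89. The epithelial list held 7 tested genes, 3 higher and 3 lower. Camera called it lower (adjusted p 0.0129, estimated-correlation adjusted p 0.138) although its median log2 was 0.01 and its mean 0.93. The higher members were Elf3, with 0 counts in wild-type cells and at least 87.47-fold more in the knockout, Krt19 (log2 1.52) and Ocln (log2 0.65). In the mesenchymal list 6 of 10 were higher and 1 lower (median log2 0.54, camera adjusted p 0.00146, estimated-correlation adjusted p 0.103). Vimentin (Vim) rose from 2683 ± 27 to 4145 ± 135 CPM (log2 0.63), the receptor kinase Axl from 463 ± 20.8 to 759 ± 33 CPM (log2 0.71) and Twist1 from 7.59 ± 0.436 to 28.8 ± 2.5 CPM (log2 1.92), while Itga5 was lower (log2 −0.18). Of 16 matrix protease and invasion genes 10 were higher and 5 lower (median log2 0.33, camera adjusted p 0.0119, estimated-correlation adjusted p 0.103). Stromelysin Mmp3 rose from 96.3 ± 5.77 to 304 ± 24.5 CPM (log2 1.66), Adamts1 from 14.5 ± 0.493 to 58.5 ± 4.09 CPM (log2 2.01) and the hyaluronan receptor Cd44 from 498 ± 10.8 to 767 ± 26.7 CPM (log2 0.62). In the mammary driver and luminal list 7 of 10 were lower and 2 higher (median log2 −0.39, camera adjusted p 0.0432, estimated-correlation adjusted p 0.198). Estrogen receptor Esr1 fell from 3.27 ± 0.274 to 0.0817 CPM (log2 −5.12) and the casein gene Csn3 fell (log2 −0.70), with Myc and Lif higher (log2 0.67 and 0.31). The luminal call was lost without wild-type replicate 9 (adjusted p 0.0573) or 12 (adjusted p 0.086). Exceptions within these lists were named after their values were seen.

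Endoplasmic reticulum chaperones and NRF2 targets were mostly lower, and heat shock proteins mostly higher, and the numbers of genes were the same adjusted over the list alone. Of the listed chaperones 12 of 17 were lower and 1 higher (median log2 −0.55, camera adjusted p 5.71e-05, estimated-correlation adjusted p 0.367). Pdia4, a disulfide isomerase, fell from 1785 ± 47.3 to 1066 ± 47.8 CPM (log2 −0.74, SE 0.038, adjusted p 4.15e-16), and the chaperone Hyou1 from 1300 ± 107 to 680 ± 31.6 CPM (log2 −0.93), with Manf at log2 −0.66. The sensor Atf6 was the higher member (log2 0.43). Among heat shock proteins 9 of 15 were higher and 1 lower (median log2 0.14, camera adjusted p 0.00711, estimated-correlation adjusted p 0.103). The collagen chaperone Serpinh1, which itself works in the endoplasmic reticulum, rose from 145 ± 7.3 to 478 ± 31.8 CPM (log2 1.72, SE 0.047, adjusted p 8.26e-22), with Hspb1 (log2 1.36) and Hspa8 (log2 0.70), against Cryab (log2 −0.18). Targets of NRF2, the antioxidant transcription factor, were mostly lower, 13 of 21 with 3 higher (median log2 −0.28, camera adjusted p 0.0292, estimated-correlation adjusted p 0.103). Gsta4, which detoxifies lipid peroxidation products, fell from 9.86 ± 1.02 to 1.61 ± 0.215 CPM (log2 −2.61, SE 0.16, adjusted p 2.92e-14), Taldo1 of the pentose phosphate pathway from 198 ± 12 to 94.5 ± 7.99 CPM (log2 −1.06), and ferritin light chain Ftl1 had a log2 of −0.50. Higher members were Nfe2l2, which encodes NRF2, with Gsr and Tkt (log2 0.30, 0.49 and 0.43). The exceptions Atf6, Cryab, Nfe2l2, Gsr and Tkt were named after their values were seen.

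No mitochondrial list was called by camera. The peroxide and superoxide list had 6 genes higher and 11 lower of 20 (median log2 −0.20, camera adjusted p 0.276). In it catalase (Cat) fell from 114 ± 5.14 to 57.7 ± 5.56 CPM (log2 −0.98, SE 0.05, adjusted p 5.54e-16) and Prdx4, the peroxiredoxin of the endoplasmic reticulum, rose from 23.8 ± 0.899 to 47.4 ± 3.18 CPM (log2 0.99). Of 13 subunits encoded by mitochondrial DNA 8 were lower and 0 higher, 7 when adjusted over the list alone (median log2 −0.47, camera adjusted p 0.197). mt-Cytb fell from 4463 ± 790 to 2607 ± 298 CPM (log2 −0.78, SE 0.121, adjusted p 0.000111) and mt-Nd4 from 2572 ± 440 to 1555 ± 214 CPM (log2 −0.73, adjusted p 0.000239). These 13 genes made up 2.75 ± 0.44% of counts in untreated wild-type and 1.97 ± 0.244% in untreated knockout libraries. Some share reads with nuclear copies on chromosome 1, which adds uncertainty to each. Nuclear complex I subunits went both ways, 9 higher and 10 lower of 36, 8 and 10 adjusted over the list alone (median log2 −0.03, camera adjusted p 0.869), with Ndufb5 at log2 0.23 and Ndufa6 at 0.24. For complexes II to V 22 of 39 were higher and 3 lower (median log2 0.14, camera adjusted p 0.22), among them the ATP synthase subunits Atp5j2 (log2 0.44) and Atp5b (log2 0.23). In the uncoupling and carrier list 4 of 11 were higher and 2 lower (median log2 −0.00, mean −0.48, camera direction up, adjusted p 0.283). There Ucp2 rose from 151 ± 8.95 to 299 ± 10.1 CPM (log2 0.98, SE 0.043, adjusted p 1.32e-17) and the adenine nucleotide carrier Slc25a4 from 290 ± 7.49 to 459 ± 14.6 CPM (log2 0.66). The biogenesis list had 5 higher and 1 lower of 14 (median log2 0.10, mean −0.48, direction up, camera adjusted p 0.704). The lower one was the coactivator Ppargc1a, named after its values were seen, which had 0 counts in knockout cells, at least 67.38-fold fewer. Mitochondrial dynamics and mitophagy genes were 4 higher and 10 lower of 18 (median log2 −0.15, camera adjusted p 0.338). Except where stated, these counts were the same adjusted over the list alone.

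The remaining lists were not called either, and their camera adjusted p follows each median log2, with numbers that were the same adjusted over the list alone. Metabolic lists were TCA cycle (11 higher and 3 lower of 22, 0.08, adjusted p 0.283), glycolysis (9 and 4 of 20, 0.10 with mean −0.24 and direction up, 0.945), fatty acid oxidation (4 and 3 of 16, −0.02 with mean 0.00 and direction up, 0.945) and cholesterol synthesis (3 and 14 of 23, −0.24, 0.158). Stress and death lists were p53 targets (11 and 7 of 23, 0.13 with direction down, 0.945), the BCL2 family (1 and 7 of 12, −0.17, 0.493), the integrated stress response (11 and 6 of 21, 0.22, 0.647) and hypoxia-inducible genes (8 and 3 of 16, 0.17, 0.594). Adhesion and signalling lists were extracellular matrix (8 and 6 of 18, 0.01, 0.475), integrins and focal adhesion (4 and 8 of 17, −0.07, 0.197), actin cortex (8 and 6 of 18, 0.04, 0.433), TGF-beta targets (7 and 6 of 19, 0.01 with mean −0.04 and direction down, 0.997) and YAP targets (7 and 5 of 14, 0.20 with mean −0.07 and direction up, 0.647). MHC class I genes had 6 higher and 2 lower of 16 (0.08, 0.575). Markers of other cells were basal (0 and 1 of 1, −0.37, 0.535), fibroblast (0 and 2 of 2, −0.88, 0.433), immune (0 and 1 of 2, 0.03 with direction down, 0.547) and endothelial (2 and 1 of 3, 1.21 with direction down, 0.419). No list median moved when members with 3 counts or fewer in a group were set to their bound.

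**Figure D3:**
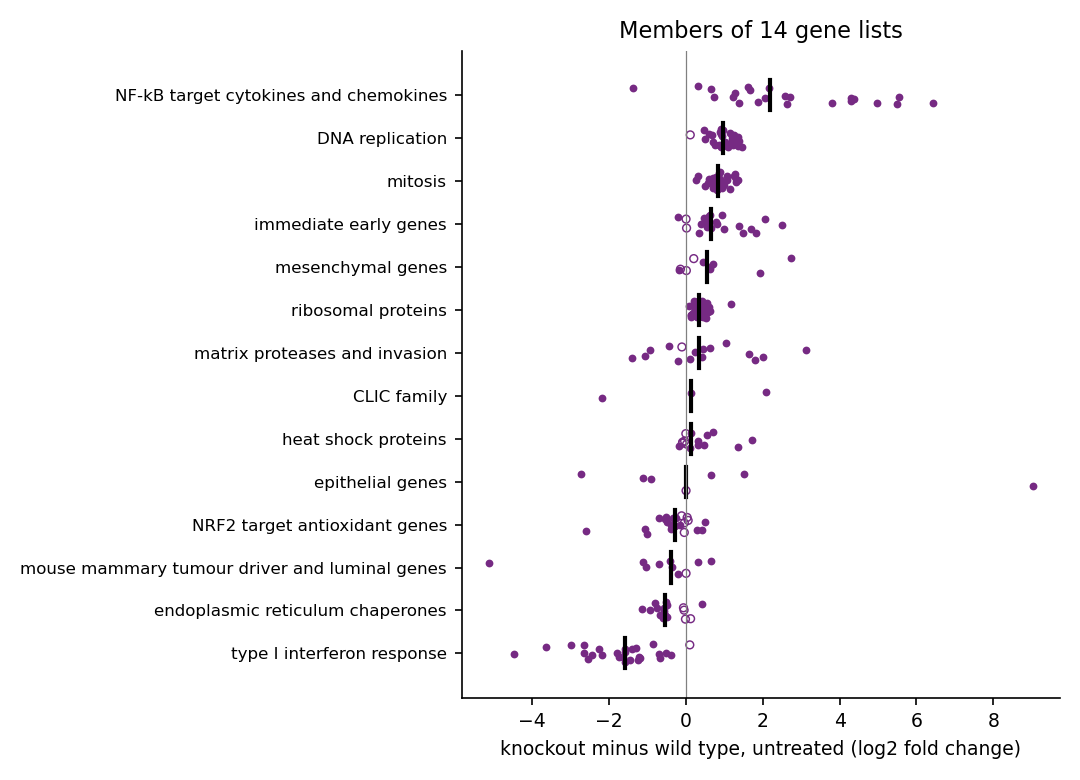
Log2 fold change of each tested member of 14 gene lists, knockout against wild type, with medians as bars. The median was 0.97 for DNA replication and −1.57 for the interferon response in untreated cells.

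Does the genotype difference look the same in cells treated with H2O2? These are separate libraries of the same lines. Of the 8 leading increases 5, and of the 8 leading decreases 7, had also led without treatment. By camera at its preset correlation proliferation genes were again higher and interferon-stimulated genes lower, and subunits encoded by mitochondrial DNA and cholesterol synthesis genes were called too. With the estimated correlation no list held (lowest adjusted p 0.0789). Of 13085 genes 8558 differed (65.4%), 4315 higher and 4243 lower in knockout cells. Of these 5229 were under 1.5-fold and 1820 reached 2-fold, 916 higher and 904 lower.

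Wnt10a was at least 304.0-fold higher in treated knockout cells, at 15.4 ± 0.666 CPM against 0 (log2 10.81, SE 0.891, adjusted p 3.56e-06). Fcho1, an endocytic adaptor, was at least 246.9-fold higher (log2 10.50), Tmem26 at least 211.8-fold (log2 10.28), Crtam at least 156.1-fold (log2 9.84) and Elf3, an epithelial transcription factor, at least 131.1-fold (log2 9.60). The ratio for Gdf15 was 1052 (188.2 to 41600, log2 9.45). For the neuronal-type glucose transporter Slc2a3, which rose from 0.151 ± 0.0637 to 61.6 ± 1.88 CPM, it was 405.4 (213.2 to 887.5, log2 8.59, adjusted p 5.29e-11), and for Col8a1 it was 334.8 (114.1 to 1627, log2 8.16). Among decreases Fndc3c1 fell at least 341.2-fold (log2 −11.50), Mid2 at least 284.1-fold (log2 −11.23), Tmtc2 at least 210.8-fold (log2 −10.80), Trim44 at least 165.4-fold (log2 −10.45), Thrb at least 165.2-fold (log2 −10.45), Ankrd29 at least 137.9-fold (log2 −10.19) and Ephb2 at least 134.6-fold (log2 −10.15). Bcat1 fell with a ratio of 1378 (247 to 54440, log2 −9.99). Clic1 (log2 0.24, SE 0.037, adjusted p 1.56e-06) and Clic5 (log2 2.06, SE 0.447, adjusted p 0.000212) were higher again.

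Camera called 15 lists at its preset correlation and 0 with the estimated one (lowest adjusted p 0.0789), and fry called 35. Mitochondrial DNA-encoded subunits were now called: 10 of 13 lower and 0 higher, also adjusted over the list alone (median log2 −0.95, camera adjusted p 0.0209, estimated-correlation adjusted p 0.543). mt-Cytb fell from 4713 ± 212 to 2055 ± 173 CPM (log2 −1.20, SE 0.134, adjusted p 6.53e-06), mt-Atp8 from 1035 ± 110 to 486 ± 49.1 CPM (log2 −1.09, SE 0.129, adjusted p 1.1e-05), and mt-Nd1 from 3001 ± 70.5 to 1740 ± 162 CPM (log2 −0.79). The 13 genes made up 2.90 ± 0.116% of counts in treated wild-type and 1.63 ± 0.125% in treated knockout libraries. Nuclear subunits read beside them were Ndufb5 (log2 0.32), Ndufs6 (log2 −0.41), Atp5j2 (log2 0.41) and Uqcrfs1 (log2 0.35), and carriers were Ucp2 (log2 0.87) and Slc25a4 (log2 0.72). Cholesterol synthesis genes were lower, 18 of 23 with 2 higher, also adjusted over the list alone (median log2 −0.40, camera adjusted p 0.0186, estimated-correlation adjusted p 0.559). Among them the sterol isomerase Ebp fell from 58.7 ± 2.94 to 32.8 ± 3.29 CPM (log2 −0.84, SE 0.061, adjusted p 1.65e-12) and the methyl sterol oxidase Msmo1 was lower (log2 −0.64).

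The other 13 called lists had been called without treatment, and except where given the numbers here and below were the same adjusted over the list alone. DNA replication was 29 higher and 0 lower of 30 (median log2 0.97, camera adjusted p 7.11e-22, estimated-correlation adjusted p 0.0875), led by Rrm2 (log2 1.39), Uhrf1 (log2 1.10) and the clamp loader subunit Rfc5 (log2 1.47). Mitosis was 30 of 30 higher (median log2 0.86, camera adjusted p 8.81e-17, estimated-correlation adjusted p 0.176), with Anln (log2 0.96), Birc5 (log2 1.38) and Ccna2 (log2 1.27). Ribosomal proteins were 44 higher and 0 lower of 48 (median log2 0.33, camera adjusted p 6.13e-07, estimated-correlation adjusted p 0.543), with Rpl22 (log2 1.15), Rpl3 (log2 0.62) and Rpl7 (log2 0.47). Interferon genes were 26 of 27 lower and 0 higher (median log2 −1.79, camera adjusted p 9.55e-20, estimated-correlation adjusted p 0.0789). Ifi44 fell from 20.8 ± 1.72 to 1.11 ± 0.0601 CPM (log2 −4.21, SE 0.141, adjusted p 4.21e-20), with Oas1a, which senses double-stranded RNA (log2 −1.92), and Usp18 (log2 −2.83). NF-kB targets were 21 higher and 1 lower of 23 (median log2 2.25, camera adjusted p 8.87e-06, estimated-correlation adjusted p 0.543), with Birc3 (log2 1.31), Tnf (log2 4.56) and Vcam1 (log2 2.25). Immediate early genes were 17 higher and 0 lower of 21, 18 and 0 adjusted over the list alone (median log2 0.63, camera adjusted p 0.00454, estimated-correlation adjusted p 0.409), with Egr2 (log2 2.38), Egr3 (log2 1.85) and Dusp1 (log2 0.91).

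Mesenchymal genes were 6 higher and 1 lower of 10 (median log2 0.51, camera adjusted p 0.00084, estimated-correlation adjusted p 0.145), with Twist1 (log2 1.99), Axl (log2 0.70) and Vim (log2 0.63). Matrix proteases were 9 higher and 5 lower of 16, 9 and 6 adjusted over the list alone (median log2 0.29, camera adjusted p 0.0211, estimated-correlation adjusted p 0.185), with Adamts1 (log2 1.76), Mmp3 (log2 1.55) and Cd44 (log2 0.62). Luminal genes were 7 lower and 2 higher of 10 (median log2 −0.44, camera adjusted p 0.0381, estimated-correlation adjusted p 0.199), with Krt18 (log2 −1.03), cyclin D1 (Ccnd1, log2 −0.55) and Esr1 (ratio 119.4, 21.14 to 4742, log2 −6.46). Heat shock proteins were 8 higher and 3 lower of 15, 9 and 4 adjusted over the list alone (median log2 0.19, camera adjusted p 0.0215, estimated-correlation adjusted p 0.199), with Serpinh1 (log2 1.76), Hspb1 (log2 1.27) and Hspa8 (log2 0.67). Chaperones of the endoplasmic reticulum were 12 lower and 2 higher of 17 (median log2 −0.46, camera adjusted p 0.00155, estimated-correlation adjusted p 0.543), with Pdia4 (log2 −0.68), calreticulin (Calr, log2 −0.56) and Pdia3 (log2 −0.58). NRF2 targets were 13 lower and 4 higher of 21 (median log2 −0.29, camera adjusted p 0.0381, estimated-correlation adjusted p 0.176), with Taldo1 (log2 −1.05), Gsta4 (log2 −2.33) and Gstm1 (log2 −0.51). Prdx4 (log2 1.06) and Cat (log2 −0.96) stood as in untreated cells. The CLIC list was 2 higher and 1 lower of 3, and was called lower (median log2 0.24, mean 0.06, camera adjusted p 0.0352, estimated-correlation adjusted p 0.177). Without knockout replicate 8 the CLIC, NRF2 and luminal calls were each lost at adjusted p 0.0508, and the luminal call was also lost without wild-type replicate 12 (adjusted p 0.0587). The epithelial list was not called with H2O2 (adjusted p 0.0538).

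How many of these differences recur between the 2 genotype comparisons? Genes were called in both for 7659, of which 7656 had the same sign, 3901 higher and 3755 lower in knockout cells. Independent sets would share 1464 higher and 1397 lower, but these compare the same lines and are not independent. A further 1087 were called only without treatment and 899 only with H2O2. Log2 fold changes correlated with a Pearson coefficient of 0.946 and a Spearman coefficient of 0.915 over all tested genes, which are not independent replicates. The 3 genes with opposite signs, named after their values were seen, were Prr12 (log2 0.13 and −0.16), Tmsb10, which binds actin monomers (log2 0.21 and −0.30), and the predicted gene Gm18588 (log2 0.39 and −0.51).

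**Figure D4:**
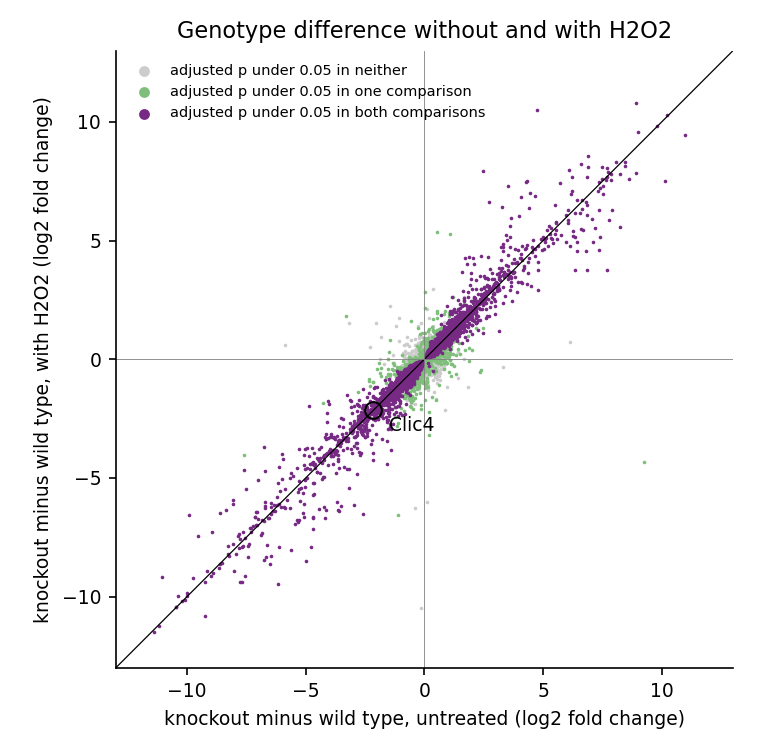
Log2 fold change of knockout against wild type without treatment and with H2O2 for each tested gene, coloured by the comparisons in which adjusted p was under 0.05. Both comparisons called 7659 genes.

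Which genes does H2O2 change in wild-type cells after 24 h? Very few passed. A gene of little-known function rose, and a gene of protein quality control in the endoplasmic reticulum fell. As a group, endoplasmic reticulum chaperones leaned lower and replication genes higher by camera at its preset correlation, which did not hold with the estimated one (adjusted p 0.126 and 0.44). The quasi-likelihood test called 2 genes, 1 higher and 1 lower, with 847 genes under an unadjusted p of 0.05 where 654 are expected by chance. DESeq2 called 9, and limma-trend on RPKM values called 0. Wdr54 rose from 15.1 ± 1.23 to 20.3 ± 1.39 CPM (log2 0.42, SE 0.071, adjusted p 0.0273). Selenos, a selenoprotein of the degradation complex in the endoplasmic reticulum, fell from 77.2 ± 4.97 to 64.4 ± 2.83 CPM (log2 −0.26, SE 0.045, adjusted p 0.0273). Both calls were lost when any of replicates 5, 9, 10, 11, 14, 15 or 16 was left out, with log2 between 0.38 and 0.42 for Wdr54 and between −0.27 and −0.22 for Selenos. Serp1 (log2 −0.23, adjusted p 0.082), Mcm7 (log2 0.20, adjusted p 0.154), Surf4 (log2 −0.19, adjusted p 0.154), Car6 (log2 −0.35, adjusted p 0.164) and Ccnf (log2 0.23, adjusted p 0.226) had the next smallest p and did not pass. Clic1 (log2 −0.03, adjusted p 0.953) and Clic5 (log2 0.30, adjusted p 0.968) did not pass. Among the genes of smallest p some passed without 1 library: Car6 without replicate 13 (log2 −0.43), Mcm7 without 4, Serp1 without 4, 12 or 13, and Surf4 without 12 or 13.

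Camera called 8 lists in wild-type cells at its preset correlation, and 0 with the estimated correlation (lowest adjusted p 0.126) or by fry. No member of a called list passed adjusted over all genes, nor except where given adjusted over the list alone. Endoplasmic reticulum chaperones were lower by a median log2 of −0.13 (camera adjusted p 3.03e-20, estimated-correlation adjusted p 0.126), with 0 higher and 11 lower adjusted over the list alone. Their members included Dnajb9 (log2 −0.23, adjusted p 0.241), Hspa5, the chaperone BiP, at 3809 ± 216 and 3358 ± 230 CPM (log2 −0.18, adjusted p 0.273), and Manf (log2 −0.17, adjusted p 0.344). Dnajb9 passed without replicate 4 or 12, Hspa5 without 12 or 13 and Manf without 12. DNA replication was higher (median log2 0.08, camera adjusted p 7.09e-09, estimated-correlation adjusted p 0.44, 4 higher and 0 lower adjusted over the list alone), with Mcm7, Uhrf1 (log2 0.17) and Mcm4 (log2 0.15). Mitosis was higher (median log2 0.07, camera adjusted p 1.08e-05, estimated-correlation adjusted p 0.673), with Plk1 (log2 0.18), Kif23 (log2 0.16) and Aurkb (log2 0.17). Integrated stress response genes were lower (median log2 −0.07, mean −0.00, camera adjusted p 0.000152, estimated-correlation adjusted p 0.673, 0 higher and 1 lower adjusted over the list alone), with Asns (log2 −0.14), Slc7a5 (log2 −0.12) and Sesn2 (log2 −0.19). Glycolysis was higher (median log2 0.06, camera adjusted p 0.00122, estimated-correlation adjusted p 0.673), with Pfkp (log2 0.09), Pfkm (log2 0.08) and Gpi1 (log2 0.08). Cholesterol synthesis was higher (median log2 0.05, camera adjusted p 0.00608, estimated-correlation adjusted p 0.673), with Hsd17b7 (log2 0.16) and Lss (log2 0.13). Matrix proteases were higher (median log2 0.02, camera adjusted p 0.026, estimated-correlation adjusted p 0.44, 3 higher and 0 lower adjusted over the list alone), with Adamts1 (log2 0.25), Mmp3 (log2 0.19) and S100a4 (log2 0.19). Complex I subunits were lower (median log2 −0.04, camera adjusted p 0.0436, estimated-correlation adjusted p 0.673), with Ndufs3 (log2 −0.12), Ndufc2 (log2 −0.12) and Ndufs5 (log2 −0.13).

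Several of these list calls hung on single libraries in wild-type cells. The complex I call was lost without replicate 5 (adjusted p 0.0507), 9 (0.187), 10 (0.0859), 12 (0.0888), 13 (0.459) or 14 (0.471). The matrix protease call was lost without 11 (adjusted p 0.132), 12 (0.354), 14 (0.0562) or 15 (0.0526), and the cholesterol call without 9 (0.178), 14 (0.117) or 16 (0.0684). Glycolysis was lost without 11 (adjusted p 0.168) and mitosis without 12 (0.133). Genes of oxidative phosphorylation and peroxide handling given by rule did not pass either: mt-Nd3 (log2 −0.35, adjusted p 0.53), mt-Nd4l (log2 0.25), Cox5b (log2 −0.13), Uqcrq (log2 −0.14), Ucp2 (log2 0.11), Slc25a12 (log2 −0.10), Srxn1 (log2 −0.14), Tkt (log2 0.10), Cat (log2 −0.12, adjusted p 0.695) and Prdx2 (log2 0.09).

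Which genes does H2O2 change in knockout cells? The 7 genes called all fell. They included a ribosomal protein, a nuclear import carrier, a metallothionein and acidic nuclear proteins. As groups, subunits encoded by mitochondrial DNA and by nuclear genes of complexes II to V leaned lower by camera at its preset correlation, and neither held with the estimated one (adjusted p 0.652 each). The test had 1041 genes under an unadjusted p of 0.05, while limma-voom called 11 (1 higher and 10 lower, all 7 shared). DESeq2 called 53 (18 higher and 35 lower, 5 of the 7 shared), and a fit of the knockout libraries alone called 7 (4 higher and 3 lower, 2 shared). Rpl5 fell from 269 ± 22.5 to 187 ± 7.2 CPM (log2 −0.52, SE 0.074, adjusted p 0.0241), although its pseudogenes share reads with it. The importin Kpna2 fell from 28.7 ± 1.9 to 20.8 ± 1.87 CPM (log2 −0.46, adjusted p 0.0241), and metallothionein Mt1 from 201 ± 10.9 to 169 ± 4.88 CPM (log2 −0.25, adjusted p 0.0241). The membrane-bound growth cone protein Basp1 fell from 108 ± 8.38 to 88.4 ± 5.46 CPM (log2 −0.28, adjusted p 0.0243), parathymosin (Ptms) from 190 ± 6.95 to 159 ± 11.1 CPM (log2 −0.25, adjusted p 0.0243), and Anp32b from 546 ± 14.9 to 472 ± 14.2 CPM (log2 −0.21, adjusted p 0.0243). A predicted gene, Gm8186, also fell (log2 −0.67), named after its values were seen. Leaving out single libraries lost Anp32b (replicates 1, 2, 4, 5, 7 or 8, log2 −0.23 to −0.19), Basp1 (4, 7 or 8, log2 −0.27 to −0.23), Kpna2 (4, 7 or 8, log2 −0.46 to −0.40), Mt1 (4, 5, 7 or 8, log2 −0.27 to −0.22), Ptms (1, 4, 5 or 8, log2 −0.26 to −0.20) and Rpl5 (4, 5 or 8, log2 −0.51 to −0.50). Without replicate 8 none passed, and without replicate 15 the number was 21, mt-Atp8 among them.

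Camera called 12 lists in knockout cells at its preset correlation and 0 with the estimated one (lowest adjusted p 0.205) or by fry. No member of these lists passed adjusted over all genes, nor except where given adjusted over the list alone. Mitochondrial DNA-encoded subunits were lower (median log2 −0.29, camera adjusted p 1.63e-08, estimated-correlation adjusted p 0.652, 0 higher and 5 lower adjusted over the list alone). mt-Atp8 stood at 849 ± 121 and 486 ± 49.1 CPM (log2 −0.80, SE 0.128, adjusted p 0.0563), with mt-Nd6 (log2 −0.48, adjusted p 0.397) and mt-Nd2 (log2 −0.33, adjusted p 0.446). Complexes II to V were lower (median log2 −0.05, camera adjusted p 2.48e-05, estimated-correlation adjusted p 0.652), with Atp5g2 (log2 −0.29), Cox5b (log2 −0.19) and Atp5j (log2 −0.11). Complex I was lower (median log2 −0.04, camera adjusted p 0.0103, estimated-correlation adjusted p 0.652, 0 higher and 1 lower adjusted over the list alone), with Ndufs6 (log2 −0.30, adjusted p 0.137), Ndufa1 (log2 −0.24) and Ndufa12 (log2 −0.19). Hypoxia-inducible genes were higher (median log2 0.11, camera adjusted p 1.05e-05, estimated-correlation adjusted p 0.652), with Kdm3a (log2 0.12), Ndrg1 (log2 0.12) and Egln1 (log2 0.13). Glycolysis was higher (median log2 0.05, camera adjusted p 0.0067, estimated-correlation adjusted p 0.652), with Gpi1 (log2 0.09), Pfkl (log2 0.10) and Aldoa (log2 0.09). Cholesterol synthesis was lower (median log2 −0.07, camera adjusted p 0.0025, estimated-correlation adjusted p 0.652), with Insig1 (log2 −0.20), Sc5d (log2 −0.18) and Dhcr7 (log2 −0.20).

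Proliferation lists were again slightly higher in treated knockout cells. DNA replication had a median log2 of 0.08 (camera adjusted p 2.74e-07, estimated-correlation adjusted p 0.652), with Mcm10 (log2 0.23), Mcm7 (log2 0.11) and Prim1 (log2 0.19). Mitosis had a median log2 of 0.06 (camera adjusted p 0.00101, estimated-correlation adjusted p 0.652), with Top2a (log2 0.14), Anln (log2 0.10) and Mki67 (log2 0.16). Endoplasmic reticulum chaperones were lower (median log2 −0.05, camera adjusted p 0.00398, estimated-correlation adjusted p 0.652), with Sdf2l1 (log2 −0.17), Calr (log2 −0.11) and Dnajb11 (log2 −0.13). Epithelial genes were higher (median log2 0.12, camera adjusted p 0.000374, estimated-correlation adjusted p 0.205, 2 higher and 0 lower adjusted over the list alone), with Krt18 (log2 0.13, adjusted p 0.288), Dsp (log2 0.12) and Elf3 (log2 0.57). Integrated stress response genes were higher (median log2 0.05, camera adjusted p 0.0103, estimated-correlation adjusted p 0.702), with Shmt2 (log2 0.13), Atf3 (log2 0.35) and Cebpg (log2 0.10). NF-kB targets were higher (median log2 0.13, camera adjusted p 0.0103, estimated-correlation adjusted p 0.702), with Cxcl2 (log2 0.50), Tnfaip3 (log2 0.25) and Birc3 (log2 0.12). Both of the last calls rested on untreated replicate 4, whose NF-kB targets were low: without it their directions reversed and adjusted p became 0.75 for the integrated stress response and 0.0763 for NF-kB targets.

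Other list calls in knockout cells were also lost without single libraries: mitosis without replicate 3 (adjusted p 0.351) or 5 (0.101), cholesterol without 4 (0.365), endoplasmic reticulum chaperones without 8 (0.0869), glycolysis without 2 (0.276), 5 (0.161) or 8 (0.105), and complex I without 1 (0.0528) or 8 (0.0697). The integrated stress response call was also lost without 8 (adjusted p 0.162) and the NF-kB call without 5 (0.064) or 8 (0.18). The carriers Slc25a5 (log2 0.10) and Slc25a4 (log2 0.05), the NRF2 targets ferritin heavy chain Fth1 (log2 −0.14, adjusted p 0.274) and Tkt (log2 0.12), the redox genes Txn1 (log2 −0.12) and Glrx2 (log2 −0.22), and Clic1 (log2 0.07, adjusted p 0.657) and Clic5 (log2 0.29, adjusted p 0.89) did not pass.

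Is there a treatment effect shared by both genotypes? A cyclin that is made in the G2 phase was higher. By camera at its preset correlation replication genes leaned higher and chaperones lower, and neither held with the estimated correlation (adjusted p 0.222 each). The average of the 2 treatment effects called 1 gene, with 1163 under an unadjusted p of 0.05, while DESeq2 called 42 that did not include it, since its independent filtering left that gene without an adjusted p. Ccnf, cyclin F, was higher with H2O2 (29.1 ± 1.12 to 34.1 ± 1.56 CPM in wild-type and 47.6 ± 0.91 to 54.2 ± 1.06 CPM in knockout cells, log2 0.21, SE 0.036, adjusted p 0.0496). Mcm7 (log2 0.15, adjusted p 0.0803), Selenos (log2 −0.17, adjusted p 0.0803), Gsta1 (log2 −0.25, adjusted p 0.134), Wdr54 (log2 0.25, adjusted p 0.134) and Sdf2l1 (log2 −0.16, adjusted p 0.134) did not pass, nor did Clic4 (log2 −0.01, adjusted p 0.973), Clic1 (log2 0.02, adjusted p 0.854) and Clic5 (log2 0.29, adjusted p 0.855). The Ccnf call was lost without any of replicates 1, 2, 4, 5, 7, 8, 9, 10, 13, 15 or 16 (log2 0.20 to 0.21). Without replicate 12 Gsta1 (log2 −0.27), Selenos (log2 −0.19) and Wdr54 (log2 0.28) passed, and without 3 Mcm7 did (log2 0.15).

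For the average effect camera called 10 lists, 0 with the estimated correlation (lowest adjusted p 0.222) and 0 by fry. Lower lists were endoplasmic reticulum chaperones (median log2 −0.09, camera adjusted p 1.53e-15, 14 lower adjusted over the list alone), complexes II to V (median log2 −0.03, camera adjusted p 0.000196), complex I (median log2 −0.04, camera adjusted p 0.000825, 1 lower adjusted over the list alone) and mitochondrial DNA-encoded subunits (median log2 −0.13, camera adjusted p 0.000318, 1 lower adjusted over the list alone). Higher lists were DNA replication (median log2 0.08, camera adjusted p 1.2e-14, 6 higher adjusted over the list alone), mitosis (median log2 0.07, camera adjusted p 5.29e-08, 3 higher adjusted over the list alone), hypoxia-inducible genes (median log2 0.07, camera adjusted p 2.84e-05), glycolysis (median log2 0.05, camera adjusted p 3.41e-05, 2 higher adjusted over the list alone), epithelial genes (median log2 0.09, camera adjusted p 0.00431, 2 higher adjusted over the list alone) and matrix proteases (median log2 0.02, camera adjusted p 0.028, 2 higher adjusted over the list alone). Estimated-correlation adjusted p was 0.222 for the chaperones, replication and epithelial lists, 0.342 for proteases, and 0.397 or 0.398 for the rest. The protease call was lost without replicate 7 (adjusted p 0.0834), 11 (0.0919) or 12 (0.159).

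Does loss of CLIC4 change the answer to H2O2? No single gene passed. Most genes nearest to it fell with H2O2 in knockout cells, an effect this test includes. By camera at its preset correlation subunits encoded by mitochondrial DNA and cholesterol synthesis genes leaned lower with H2O2 in knockout than wild-type cells. Neither held with the estimated correlation (adjusted p 0.904 each) or by fry. The interaction test of edgeR called 0 genes, with 808 under an unadjusted p of 0.05, while DESeq2 called 15. Ptms (log2 −0.33, adjusted p 0.148), Mt1 (log2 −0.31, adjusted p 0.148), Rpl5 (log2 −0.57, adjusted p 0.156), Anp32b (log2 −0.22, adjusted p 0.455) and Parp3 (log2 −0.25, adjusted p 0.455) had the smallest p and did not pass, and Rpl5 passed without replicate 15 (log2 −0.50). The interaction was log2 0.04 for Clic4 (adjusted p 0.972), 0.10 for Clic1 (adjusted p 0.823) and −0.02 for Clic5 (adjusted p 1).

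Camera called 7 lists for the interaction, 0 with the estimated correlation (lowest adjusted p 0.904) and 0 by fry. Mitochondrial DNA-encoded subunits responded lower in knockout cells (median log2 −0.35, camera adjusted p 9.72e-07, 1 lower adjusted over the list alone), as did cholesterol synthesis (median log2 −0.14, camera adjusted p 6.32e-06) and complexes II to V (median log2 −0.04, camera adjusted p 0.0277). The integrated stress response (median log2 0.13, camera adjusted p 1.56e-06, 1 higher adjusted over the list alone), endoplasmic reticulum chaperones (median log2 0.06, camera adjusted p 0.000745), p53 targets (median log2 0.07, camera adjusted p 0.0277, 1 higher adjusted over the list alone) and hypoxia-inducible genes (median log2 0.06, camera adjusted p 0.0277) responded higher. With the estimated correlation adjusted p was 0.987 for complexes II to V and hypoxia and 0.904 for the other 5. The call for complexes II to V was lost without replicate 1 (adjusted p 0.127), 4 (0.0622), 5 (0.0697), 8 (0.213), 10 (0.0565), 11 (0.103), 12 (0.0576), 15 (0.289) or 16 (0.318). The p53 call was lost without 4 (adjusted p 0.374), 5 (0.0594), 7 (0.0542), 10 (0.0565), 12 (0.0979), 13 (0.0553) or 16 (0.0562). The hypoxia call was lost without 2 (adjusted p 0.317), 4 (0.0902), 5 (0.282), 8 (0.501), 9 (0.22), 10 (0.0541), 14 (0.0561) or 16 (0.209). The cholesterol call was lost without replicates 4 and 9 together (adjusted p 0.0649).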

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

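Of the tests in this part, the splits of the libraries and the test of neighbouring genes were planned, and all tests of library scaling, drift, replicate 4 and replicate 9 were chosen after the results were seen.

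In untreated knockout replicate 4, transcripts of NF-kB targets were low. Their mean was 3.614 on the log2 scale against 4.791 to 4.980 in the other 3 libraries, and the list's median difference was −1.071 against −0.314 for the list that followed, the integrated stress response. Wild-type RNA in the library was excluded, since genes counted in wild-type libraries alone stood at 0.2297% of their wild-type level (0.0785% to 0.218% in the other knockout libraries), and so was library scaling, which moves all lists alike, since 0 of the 38 other lists had a median within 0.5 of this one. By a log2 of more than 1, 67 genes were lower, 13 of them in this list, and 12 higher. A weaker NF-kB signal in that culture, from cell density or handling, may account for it, a hypothesis that the labels give no means to test.

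Untreated wild-type replicate 9 held transcripts of blood cells: 98 genes that stayed under 10% of its level in every other library summed to 410.3 CPM, led by S100a9 (50.6 CPM), Mpo (20.6), Lyz2 (19.4), Olfm4 (18.2) and Ngp (17.6). Of the 11 immune markers fixed beforehand, 7 were highest in this library (2 of them among those 98 genes), which fits RNA from leukocytes as a candidate source, although their sum, mostly Cd68 that all libraries express, was not. Markers of other cells were also highest there, 3 of 11 of fibroblasts (Pdgfrb 2.90 CPM, at most 0.0708 elsewhere) and 1 of 8 of endothelium (Pecam1 2.36 CPM, at most 0.347), so leukocytes need not be the whole source. A mislabelled knockout sample was excluded, as Clic4 stood at 326.7 CPM against at most 75.91 CPM in knockout libraries. Reads from another library of the same run stay open, since 0 of the labels name a run or lane.

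The genotypes differed in 8746 genes without treatment, 66.84% of those tested. Library scaling was excluded for 2-fold differences only, of which at least 1777 stayed under any single factor between the genotypes. Segmental copy number was excluded as the whole cause: 54.02% of 8716 neighbouring pairs of called genes changed in the same direction, above the 48.94% to 51.19% of 100 permutations but far under the 75% it needs. Drift between separately grown lines cannot be told apart from loss of CLIC4, because 0 of the labels name a clone. The breadth may therefore belong in part to the derivation of the lines.

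Other splits of the libraries were fitted in the same way. For the genotype comparison without treatment, 1 of 35 splits, the real one, gave as many genes (8746, highest other 0) or lists (14, highest other 13). With H2O2 the same held, for 1 of 35 splits with genes (8558, highest other 5414) and 1 of 35 with lists (15, highest other 14). The other splits that called any gene there were the 4 that set 3 wild-type libraries against the rest, so they point to the genotype. For H2O2 in knockout cells 1 of 35 gave as many genes (7, highest other 2). The genotype lists led by 1, and the 7 genes fell to 0 without replicate 8. With 12 results tried and 1 of 35 the smallest share, chance is excluded for these and both genotype gene counts only taken singly. Chance cannot be excluded for H2O2 in wild-type cells (2 genes, highest other 22, 2 of 35 splits) or for the average effect (1 gene, highest other 1, 10 of 100). For the interaction the splits say nothing, since 0 genes were called and any split (100 of 100, highest other 6) has as many. Nor can it for the lists called for H2O2 in wild-type cells (8, highest other 11, 10 of 35), H2O2 in knockout cells (12, highest other 14, 8 of 35), the average effect (10, highest other 14, 24 of 100) and the interaction (7, highest other 15, 52 of 100). Even arbitrary splits thus called several lists with camera at its preset correlation.

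Single libraries far from the other replicates of their group were sought among 443 sets of replicates of 162 named genes, where chance gives about 1 in 20. There were 29 (6.55%), and 43 sets under 20 counts were passed over. In untreated knockout replicate 4 these were Atf3 (9.681 CPM, others 18.28 to 19.99), Birc3 (17.83, others 24.35 to 25.06), Ccnd1 (297.1, others 231.5 to 238.7), Col8a1 (9.681, others 16.27 to 16.77) and Usp18 (6.343, others 3.676 to 4.051). In replicate 2 they were Axl (709.6, others 773.1 to 778), Fth1 (1769, others 1684 to 1696), Gpi1 (971.1, others 1044 to 1050) and Jup (68.8, others 77.35 to 77.91). In replicate 1 they were mt-Nd3 (75.21, others 87.91 to 90.43) and Ndufs5 (10.03, others 12.41 to 12.82), and in replicate 3 mt-Nd4l (63.29, others 78.11 to 80.03), Rrm2 (256.9, others 303.2 to 309.3) and Uqcrq (55.95, others 47.64 to 48.61). In untreated wild-type replicate 9 they were Birc3 (10.33, others 9.53 to 9.636), Egln1 (137.7, others 118.7 to 120.6), Fcho1 (1.62, others 0) and Lcp1 (31.12, others 18.35 to 20.35), in replicate 10 Plcl1 (9.494, others 8.371 to 8.556) and Slc25a12 (54.41, others 48.86 to 49.75), and in replicate 11 Car6 (23.1, others 24.62 to 24.71), Dusp6 (52.03, others 55.76 to 56.04), Ephb6 (6.47, others 8.644 to 9.046) and Uqcrq (69.56, others 79.92 to 81.21). In treated wild-type cells they were Cebpg (replicate 13, 80.94, others 74.9 to 75.08), Sdf2l1 (14, 197.3, others 216.2 to 218.3), Sc5d (15, 58.87, others 62 to 62.25), Ifi44 (16, 23.42, others 19.89 to 20.05) and Ptms (16, 183.4, others 166.4 to 168.7). Of 5 measures per library in 3 of the groups, replicate 16 also stood apart in the share of the 13 mitochondrial genes (2.727%, others 2.944 to 2.981) and in the NF-kB mean (2.4, others 2.152 to 2.18), beside replicate 4.

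The answer to H2O2 differed between genotypes for 7 lists by camera at its preset correlation: mitochondrial DNA-encoded subunits (adjusted p 9.72e-07), integrated stress response (1.56e-06), cholesterol synthesis (6.32e-06), endoplasmic reticulum chaperones (0.000745), and complexes II to V, p53 targets and hypoxia-inducible genes (0.0277 each). None passed with the estimated correlation, and 52 of 100 splits called at least 7 lists.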

How the results depend on the processing

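Leaving out replicates 4 and 9 together was the 1 alternative chosen after the data were seen. The counts for the genotype comparisons stayed within 1.5 times under every alternative except a required log2 fold change of at least 1. Without treatment they ran from 7573 (stricter filter) to 9135 (no filter) and from 8399 to 8773 without 1 library. With H2O2 they ran from 7393 to 8832 and from 7965 to 8639 without 1 library, and genes with the same sign in both from 7273 to 7669 without 1 library. The fold requirement left 1745, 1820 and 1552, by its own construction. Genes named by rule for these comparisons (others unchecked) kept direction and call under each other alternative that tested them. The fold requirement ended 25 and 24 calls. The stricter filter left Clic5, Egr2, Esr1 and Tnf untested, and the fit of only the untreated groups left out Clic5. Counts for H2O2 moved with most settings, and except for the fold requirement the cause was not tested. In wild-type cells 2 genes became 12 without a filter, 9 with DESeq2, 0 with the fold requirement, 0 with only the groups compared (967 under an unadjusted p of 0.05), 0 with limma-trend on either RPKM scale (837 and 867), and 0 without replicates 4 and 9 (696). Without 1 library they ran from 0 (any of replicates 5, 9, 10, 11, 14, 15 or 16) through 6 (without 4) and 7 (without 13) to 13 (without 12). In knockout cells 7 genes, all lower, became 27 without a filter, 53 with DESeq2 (18 higher), 7 with only the groups compared (4 higher, 2 shared), 11 with limma-voom, 3 and 4 with limma-trend on log2(RPKM + 0.1) and log2(RPKM + 1), 3 without replicates 4 and 9 and 0 with the fold requirement. Without 1 library they ran from 0 (without 8) through 1 (without 4), 4 (without 5) and 18 (without 3) to 21 (without 15). For the average effect 1 gene became 41 without a filter, 42 with DESeq2, 2 and 2 on the RPKM scales, 0 without replicates 4 and 9 (879 under an unadjusted p of 0.05) and 0 with the fold requirement. Without 1 library it ran from 0 (any of 1, 2, 4, 5, 7, 8, 9, 10, 13 or 16) through 2 (without 15) and 5 (without 12) to 7 (without 3). For the interaction 0 genes became 5 without a filter and 15 with DESeq2, and without 1 library from 0 to 3 (without 15) with 1 without 8. Independent filtering in DESeq2 left 3445, 2430 and 7504 genes with an adjusted p for H2O2 in knockout cells, the average effect and the interaction, and Ccnf was not among the 2430. Named genes that passed with DESeq2 and not in the report were Mcm7, mt-Nd3, Serp1 and Surf4 for H2O2 in wild-type cells, Fth1, Krt18, mt-Atp8 and mt-Nd6 in knockout cells, Mcm7 and Sdf2l1 for the average effect, and Anp32b, Mt1, Ptms and Rpl5 for the interaction.

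List calls depended on the correlation between genes. With the estimated one, camera called 1 list for the genotype comparison without treatment and 0 with H2O2, 0 for H2O2 in wild-type cells, 0 in knockout cells, 0 for the average effect and 0 for the interaction, and the cause was not tested. Fry, which tests another hypothesis, called 32, 35, 0, 0, 0 and 0. Size factors of DESeq2 changed none of the 6 numbers of lists called. Without 1 library the numbers ran from 13 to 15, 12 to 16, 5 (without replicate 12) to 9 (without 4), 7 (without 8) to 15, 9 to 13 and 4 (without 4) to 8. For H2O2 in knockout cells 2 lists reversed without untreated replicate 4: the integrated stress response (adjusted p 0.75, and 0.792 without both 4 and 9) and NF-kB targets (0.0763 and 0.0679). Over single libraries left out their adjusted p ran from 8.86e-06 (without 3) to 0.75 and from 4.73e-05 (without 1) to 0.18 (without 8, same direction). Near 0, uncalled log2 values of CLIC genes changed sign. Clic4 ran from −0.03642 (without 4) to 0.04582 (without 7) for H2O2 in knockout cells, from −0.03268 to 0.008358 (same libraries) for the average effect and from −0.007483 to 0.07492 (same libraries) for the interaction, with −0.03446 in knockout cells and −0.0135 for the interaction without both 4 and 9. The Clic5 interaction ran from −0.4264 (without 11) to 0.3441 (without 3), with 0.1523 and 0.03977 on the RPKM scales. Scaling by library size in place of TMM moved the median of all genes by at most 0.0328 on the log2 scale. No paired analysis was possible because the library numbers run over the whole series. Depth limits genes near the floor: of 55341 symbols 13085 had enough counts to test, and folds against groups with 0 counts are lower bounds.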

Other observations

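Of the tests in this part, both the list of genes found in 1 genotype and the copy gain test on chromosome 5 were chosen after the results were seen.

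Some genes were expressed in 1 genotype alone, with and without H2O2. With at most 3 counts summed over the other genotype, at least 1 CPM in each library and a mean of at least 3 CPM, 30 genes were found in wild-type cells alone, on 14 chromosomes, and 9 in knockout cells alone, on 7 chromosomes. The wild-type genes included receptors and enzymes: Bcat1 (33.8 CPM), Fndc3c1 (23.9), Lcp1 (21.1), Mid2 (20.4), Itga8 (18.5), Tmtc2 (15.4), Thrb (12.1), Trim44 (12.1), Ankrd29 (10.1), Ephb2 (9.61), Gata4 (8.62), the scaffold Cul9 (5.65), the kinase Cask (4.28), the coactivator Ppargc1a (3.65) and the carbonic anhydrase Car12 (3.12). The knockout genes were Gdf15 (17.4 CPM), Wnt10a (13.6), Tmem26 (10.5), the predicted gene Gm5532 (10.2), Crtam (7.70), the growth factor Ptn (7.28), Fkbp10 (5.82), Elf3 (5.41) and Otop1 (3.12).

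Genes at the end of chromosome 5 were higher in knockout cells as a block. Among 1218 windows of 50 neighbouring genes, 8 had a median log2 difference beyond the limit that 95% of 100 permutations kept to (0.3251) without treatment, and all 8 lay on chromosome 5. With H2O2 10 windows did (limit 0.3401), these 8 and 2 on chromosome 1 that were lower in knockout cells (median log2 −0.354 and −0.343). They joined to a region from 138194314 to 150993817 (mm10) with 120 tested genes and a median log2 of 0.450, against −0.0204 for the other 733 genes of the chromosome. A copy gain of this segment in the knockout line may account for it, and would give a log2 of 0.585 for 3 copies in place of 2. The region set on the untreated libraries was then read in the H2O2 libraries, where 81.67% of its genes were higher in knockout cells (98 of 120, median log2 0.498) against 45.7% in the rest of the chromosome. These libraries come from the same lines, so the test excludes noise between libraries and not other causes of a regional change, and DNA was not measured.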
